A study of Mus musculus with 6 samples.

How the data were processed

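RNA was extracted with Trizol from splenic CD4+ T cells of C57BL/6N mice after 16 h of stimulation, libraries were made at a sequencing company with a SMART-seq v4 kit for low input, and they were read on an Illumina NovaSeq sequencer. The submitters' processing notes name Trimmomatic 0.38, HISAT2 2.1.0, StringTie 2.1.3b and the mouse genome build mm10. The order in which these tools were used, their settings and the counting strand are not given in the sources used here. The authors deposited 1 table with a value in TPM (transcript abundance scaled to a fixed total per library) for each of 18025 genes in each of the 6 libraries. The same deposited table holds an adjusted p-value per gene by the authors, whose test and adjustment are not given in the sources used here. Only 5 of the 108150 TPM values were 0, so genes at 0 in some library seem to have been left out before deposit. TPM keeps no record of sequencing depth, so the precision of a value was judged from the spread between libraries alone.

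The 6 libraries fell into 2 groups, anti-CD153 and control IgG, with 3 libraries in each that the submitters call biological replicates. Values in the text are mean ± SD of TPM over the 3 libraries of a group. The comparison is anti-CD153 minus control IgG, so a positive log2 value is higher with anti-CD153. Genes with at least 1 TPM in at least 3 of the 6 libraries were tested, which kept 13324 genes and left out 4701. The test was limma 3.58.1 in R 4.3.3 on log2(TPM + 1), with a mean-dependent trend of the spread, two-sided, without a covariate, and with p adjusted over the tested genes by the method of Benjamini and Hochberg at a threshold of 0.05. Confidence intervals are 95% intervals of the limma estimate. The replicate number was not used as a covariate, since the labels name no animal or day shared by libraries of equal number. Across genes, deviations from the group means correlated at -0.34, -0.18 and 0.30 for the libraries of replicate number 1, 2 and 3. No control library correlated best with the anti-CD153 library of its own number.

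Gene lists were tested with camera in limma, with a preset correlation of 0.01 between genes, adjusted over the lists with at least 4 tested members. Camera compares a list with all other genes. Camera with an estimated correlation and fry, both in limma, were run beside it. There were 42 lists, of which 39 were tested. Lists of plasma cell, neutrophil and of erythroid and platelet markers had too few tested members. Some genes belong to several lists, such as Il2ra, Lta, Prdm1, Ctla4, Il10 and Il4ra, so the list results are not independent. The test, the filter, the lists, those alternatives chosen at the outset and the rule for naming genes were fixed before the data were examined.

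The rule named 9 genes whatever their result, then up to 12 genes per direction among those past the adjusted threshold, filled by the smallest unadjusted p because none passed. These needed all values of one group above all of the other and a mean of at least 5 TPM in the higher group. Gene models without a symbol, including those with a LOC number, ribosomal RNA and variable segments of T cell receptors or immunoglobulins were skipped there. In each list described, up to 4 members with the smallest unadjusted p were named, and markers of other cell types were given as levels. The results of some list members are not reported here. The genes of the authors' deposited adjusted p under 0.05 were named as well, a choice made after their values were seen.

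Positions are those of the RefSeq gene table of the mm10 build, counted from 1, where 17725 genes were matched by RefSeq accession or, failing that, by symbol. Transcript lengths and GC content came from the GENCODE M21 annotation of that build for 15777 genes. Exons of the 113 named genes were compared with those of other genes in that annotation, and 14 of the 111 that have exons there share at least 10% of their exon bases with another gene. The annotation the authors counted on is not given in the sources used here, so that overlap is a guide only.

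The alternatives chosen at the outset were a pseudocount of 0.1 or 5, no filter, a filter at 5 TPM, median-of-ratios scaling, quantile normalization, limma without a trend, array weights, a replicate block, leaving out each library in turn, and the 2 other list tests. Removal of the trend of transcript length and GC content from each library with mgcv 1.9.3, genes with an NM accession only, robust eBayes, and array weights estimated gene by gene were added after seeing the data. The test was tested on simulated data with the means and spread of the real genes, in 20 draws of 13324 genes with 200 changed genes. It recovered 60.9% of changes of 1 log2 unit and 96.8% of changes of 2 log2 units, 5.71% of its calls were false, and it called 0 genes and 0 lists where nothing had been changed. A list shifted by 0.5 log2 units was found in 100% of the draws. The simulation drew genes independently, so it says nothing about lists whose members vary together. It changed only genes with a mean log2(TPM + 1) above 2 and drew all libraries with equal spread. In the real data control IgG replicate 1 lay apart, so these shares need not hold there. Figures were drawn with matplotlib 3.10.9 and pandas 2.3.3 in Python 3.11.15.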

Results

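RNA sequencing measured gene expression in 6 libraries of CD4+ T cells from the spleen of C57BL/6N mice. The cells were enriched for CD153 and PD-1 at the surface and for high CD44, the phenotype of senescence-associated T cells (SA-T cells), a CD4+ population that accumulates with age. All libraries came from cells kept for 16 h with antibodies against CD3 and CD28, which trigger the T cell receptor and its costimulatory receptor. In 3 libraries the wells also carried plate-bound RM153, an antibody against CD153, and in the other 3 they carried control IgG. CD153 is the ligand of CD30 and is encoded by Tnfsf8, while CD30 is encoded by Tnfrsf8. The submitters call the 3 libraries of each group biological replicates. The sources used here do not say whether these were separate animals or separate cultures, so the p-values measure the spread between these libraries.

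The deposited table listed 18025 genes as TPM, transcript abundance scaled to a fixed total per library, and 13324 of them reached 1 TPM in at least 3 of the 6 libraries and were tested. Each library summed to between 998508 and 999440 TPM, and between 12953 and 13602 genes reached 1 TPM in it. TPM keeps no record of the number of reads, so the depth is unknown and no counting interval is given. Across genes, the correlation of log2(TPM + 1) between libraries ran from 0.958 to 0.991. Control IgG replicate 1 lay apart from the rest. It sat at -50.2 on the first principal component, which held 57.4% of the variance, and the other libraries sat between -1.02 and 21.4. Its root-mean-square distance from the median of the others was 0.54 log2 units, against 0.23 to 0.29 for the other libraries.

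The comparison of anti-CD153 with control IgG asks which transcripts differ when CD153 is engaged during activation through CD3 and CD28. Atf3, a stress- and activation-induced transcription factor, had a mean of 17.0 ± 1.01 TPM (SD, n = 3) with anti-CD153 and 5.27 ± 1.13 TPM (SD, n = 3) with control IgG. Myc, the growth regulator, stood at 78.1 ± 11.8 against 29.4 ± 12.7 TPM, and Il2ra, the alpha chain of the IL-2 receptor, at 66.7 ± 15.2 against 30.3 ± 6.13 TPM (SD, n = 3 in each group). Among gene groups, ribosome biogenesis, IL-2/STAT5 target and T cell receptor early-response genes rose with anti-CD153 by a set test with a preset correlation between genes. Cytosolic ribosomal protein genes fell by that test, a call that was lost without control IgG replicate 1, where their median log2 fold change was -0.0065. None of these group calls held with an estimated correlation, where the smallest adjusted p over the lists was 0.341.

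No gene passed a Benjamini-Hochberg adjusted p of 0.05 in limma, and the smallest adjusted p was 0.225, for Atf3. With limma array weights, which count some libraries more than others, 1699 genes passed, but only 2, Atf3 and Irf4, did so when these weights were estimated gene by gene, an alternative chosen after seeing the data. Array weights below are those of the first kind unless named gene-by-gene weights. Most of their weight lay on control IgG replicate 2 (3.80) and anti-CD153 replicate 3 (6.71). The other libraries had weights from 0.138 to 0.695, so values with array weights rest largely on these 2 libraries. At an unadjusted p under 0.05 there were 1109 genes, where chance gives 666.2. Of these, 821 were higher and 288 lower with anti-CD153, or 74.0% higher. That split was 584 higher and 492 lower (54.3% higher) after median-of-ratios scaling of the libraries, and 615 higher and 495 lower (55.4% higher) after quantile normalization. Without anti-CD153 replicate 2 it was 445 higher and 304 lower (59.4% higher). The count of 1109 was 4601 with array weights, 2015 with gene-by-gene weights, 668 without anti-CD153 replicate 1 and 458 without anti-CD153 replicate 3. All 3 values of one group lay above all 3 of the other for 2356 genes, or 17.7%, where chance gives 10%. Of them 1648 were higher and 708 lower with anti-CD153. Both chance values are averages, and genes vary together between libraries. Other ways to part the libraries into equal groups gave 93 to 1908 genes at an unadjusted limma p under 0.05. The share of non-overlapping genes was not computed for those.

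The 9 genes fixed for naming whatever their result included both partners of the CD153 pathway. Tnfsf8, which encodes CD153 (chromosome 4, 63831202 to 63861508, mm10), was abundant, with 957 ± 147 TPM with anti-CD153 and 693 ± 59.6 TPM with control IgG (SD, n = 3). Its log2 fold change of TPM + 1 was 0.46 (95% confidence interval 0.12 to 0.79), with an unadjusted limma p of 0.0140. Tnfrsf8, which encodes CD30 (chromosome 4, 145267132 to 145315164), was scarce, at 2.19 ± 0.317 against 1.20 ± 0.479 TPM (SD, n = 3). Its log2 fold change was 0.56 (0.10 to 1.02), with an unadjusted p of 0.0238, and it was 0.33 with array weights and, at this low level, 0.22 with a pseudocount of 5 and 0.88 with one of 0.1. Every value of both genes with anti-CD153 lay above every control value.

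Of the cytokine genes in this set, Il21, which encodes a helper cytokine for B cells, had the largest difference, 0.91 on the log2 scale (0.20 to 1.61), at 155 ± 45.2 against 83.9 ± 31.3 TPM (SD, n = 3). Its groups overlapped, and the unadjusted p was 0.0186. Il2, which lies on chromosome 3 near Il21, stood at 31.9 ± 6.99 against 21.4 ± 2.76 TPM, a log2 difference of 0.54 with an unadjusted p of 0.0175, or 0.84 with array weights. Ifng, which encodes interferon gamma, stood at 414 ± 50.5 against 316 ± 43.4 TPM, a log2 difference of 0.39 with an unadjusted p of 0.0312. Spp1, which encodes osteopontin and is highly expressed by SA-T cells, was the most abundant of the 9 genes, at 4551 ± 631 against 3607 ± 545 TPM. Its log2 difference was 0.34 (-0.03 to 0.70) with an unadjusted p of 0.0649, and it was 0.21 without control IgG replicate 1, 0.13 with array weights and 0.18 with gene-by-gene weights. In the GENCODE annotation, exons of another gene model on the same strand overlap 25.9% of the exon bases of Ifng and 18.8% of those of Spp1, so their values carry that uncertainty.

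Pdcd1 and Cd44, which encode sorting markers other than CD153, differed by less than the larger SD of the groups. Pdcd1, which encodes PD-1, stood at 1082 ± 197 TPM with anti-CD153 and 905 ± 301 TPM with control IgG, a log2 difference of 0.31 with an unadjusted p of 0.281. Without control IgG replicate 1 this difference was -0.0046, and without control IgG replicate 3 it was 0.50. Cd44 stood at 147 ± 6.35 against 159 ± 21.4 TPM, a log2 difference of -0.11 with an unadjusted p of 0.456, which was 0.045 with array weights and -0.011 with gene-by-gene weights. Cebpa, a transcription factor gene expressed by SA-T cells, stood at 2.47 ± 0.289 against 2.15 ± 0.287 TPM, with overlapping groups and an unadjusted p of 0.403. Leaving out 1 library put the Cd44 difference between -0.21 (without control IgG replicate 2) and -0.012 (without control IgG replicate 1). It put that of Cebpa, 0.14 with all libraries, between 0.06 (without control IgG replicate 2) and 0.21 (without anti-CD153 replicate 3). With the trend of transcript length and GC content removed, Cebpa was at 0.035 and Cd44 at -0.19. With median-of-ratios scaling they were at 0.091 and -0.17, and with a pseudocount of 5 Cebpa was at 0.063.

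**Figure D1:**
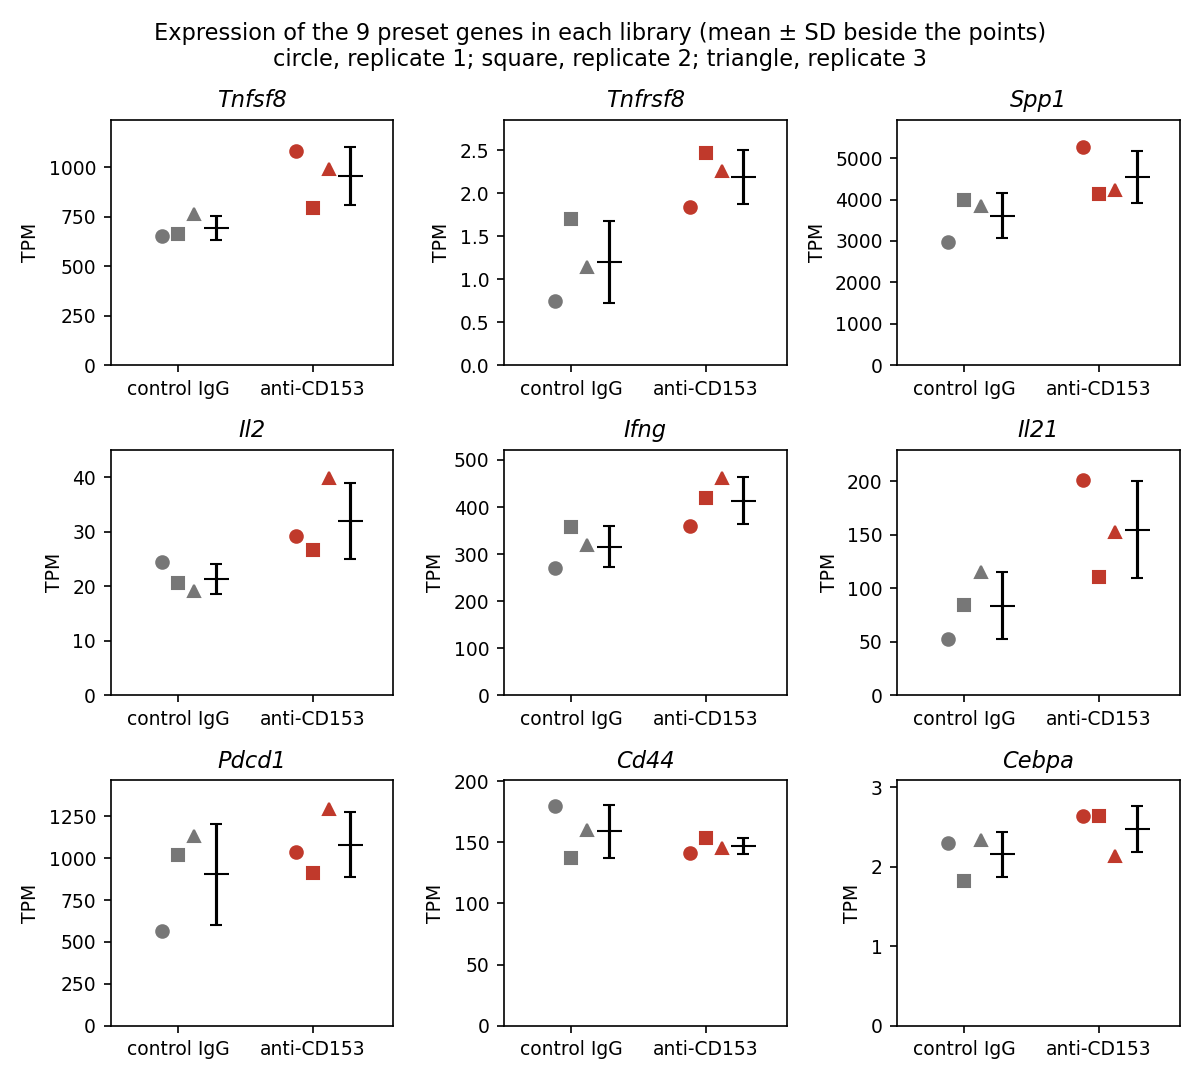
Expression in TPM (vertical axes, each from 0) of the 9 genes named whatever their result, with 1 point per library (circle, replicate 1; square, replicate 2; triangle, replicate 3), control IgG in grey and anti-CD153 in red; the black mark and bar beside the points are the mean ± SD of 3 libraries. For Tnfsf8, Tnfrsf8, Spp1, Il2 and Ifng every anti-CD153 value lies above every control value, and for Pdcd1 the lowest point is control IgG replicate 1.

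Outside this set, the 12 genes with the smallest unadjusted p among those higher with anti-CD153 in every library, with a mean of at least 5 TPM, were led by Atf3 (chromosome 1, 191170296 to 191183333), with a log2 fold change of 1.54 (1.15 to 1.93) and an unadjusted p of 1.69e-05. None of the 12 passed the adjusted threshold. Irf4 (chromosome 13, 30749233 to 30766981), a transcription factor whose level follows T cell receptor signal strength, stood at 112 ± 10.2 against 61.9 ± 4.09 TPM (log2 0.84). Ccr4 (chromosome 9, 114490316 to 114505476), a chemokine receptor of Th2 and regulatory T cells, stood at 21.3 ± 2.51 against 10.4 ± 0.959 TPM (log2 0.97). Tnfrsf4, which encodes the costimulatory receptor OX40, stood at 2031 ± 115 against 1293 ± 118 TPM (log2 0.65). Lta, which encodes lymphotoxin alpha, stood at 109 ± 14.5 against 54.9 ± 11.9 TPM (log2 0.99), and Cish, a STAT5-induced inhibitor of cytokine signalling, at 102 ± 10.7 against 50.1 ± 12.7 TPM (log2 1.03).

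The remaining genes of the 12 were Mfsd2a (log2 1.13), a lysophospholipid transporter, Ipo4 (0.89), a nuclear import receptor, Ajuba (0.81), a LIM-domain adaptor, Serpina3f (0.87), Serpina3g (0.84) and Gm29721 (1.13). With a pseudocount of 5, Mfsd2a was at 0.70 and Gm29721 at 0.73. Serpina3f and Serpina3g are neighbouring members of a multigene family on chromosome 12, and Gm29721 lies in a cluster of related genes and pseudogenes on chromosome 17, so reads of these 3 genes can be split between copies and their values are uncertain. Exons of another gene model cover 55.3% of the exon bases of Ipo4 on the same strand, with the same caveat.

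Among genes lower with anti-CD153 in every library, with a mean of at least 5 TPM with control IgG, the 12 with the smallest unadjusted p had log2 fold changes from -0.88 (Smco4) to -0.48 (2810001G20Rik), and none passed the adjusted threshold. Rgs2, a regulator of G protein signalling, stood at 34.6 ± 0.407 TPM with anti-CD153 and 54.5 ± 4.92 TPM with control IgG (log2 -0.63). Il15, which encodes a cytokine of memory T cells and NK cells, stood at 5.31 ± 0.135 against 8.92 ± 0.396 TPM (log2 -0.65, or -0.43 with a pseudocount of 5). Ly96, which encodes the TLR4 partner MD-2, had a log2 difference of -0.81 (-1.21 to -0.41), and -0.45 once the trend of transcript length and GC content was removed. Tspo, an outer mitochondrial membrane protein, stood at 649 ± 18.6 against 942 ± 145 TPM (log2 -0.53), and Neurl3, a ubiquitin ligase, at 101 ± 3.55 against 145 ± 18.0 TPM (log2 -0.50, or -0.30 with array weights). The others were Gm30603 (-0.84), Insl6 (-0.62), Pigp (-0.54), Slc36a3os (-0.52, or -0.33 with a pseudocount of 5) and BC064078 (-0.50). With that trend removed, Insl6 was at -0.39, Pigp at -0.31, Slc36a3os at -0.24 and 2810001G20Rik at -0.30. Exons of Ttc3 on the opposite strand cover 16.4% of the exon bases of Pigp, and without strand in the counting the values of such pairs are uncertain. The same holds for Lef1 (13.7%), Nfkb2 (11.6%) and Rgs16 (10.1%), which are described below.

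**Figure D2:**
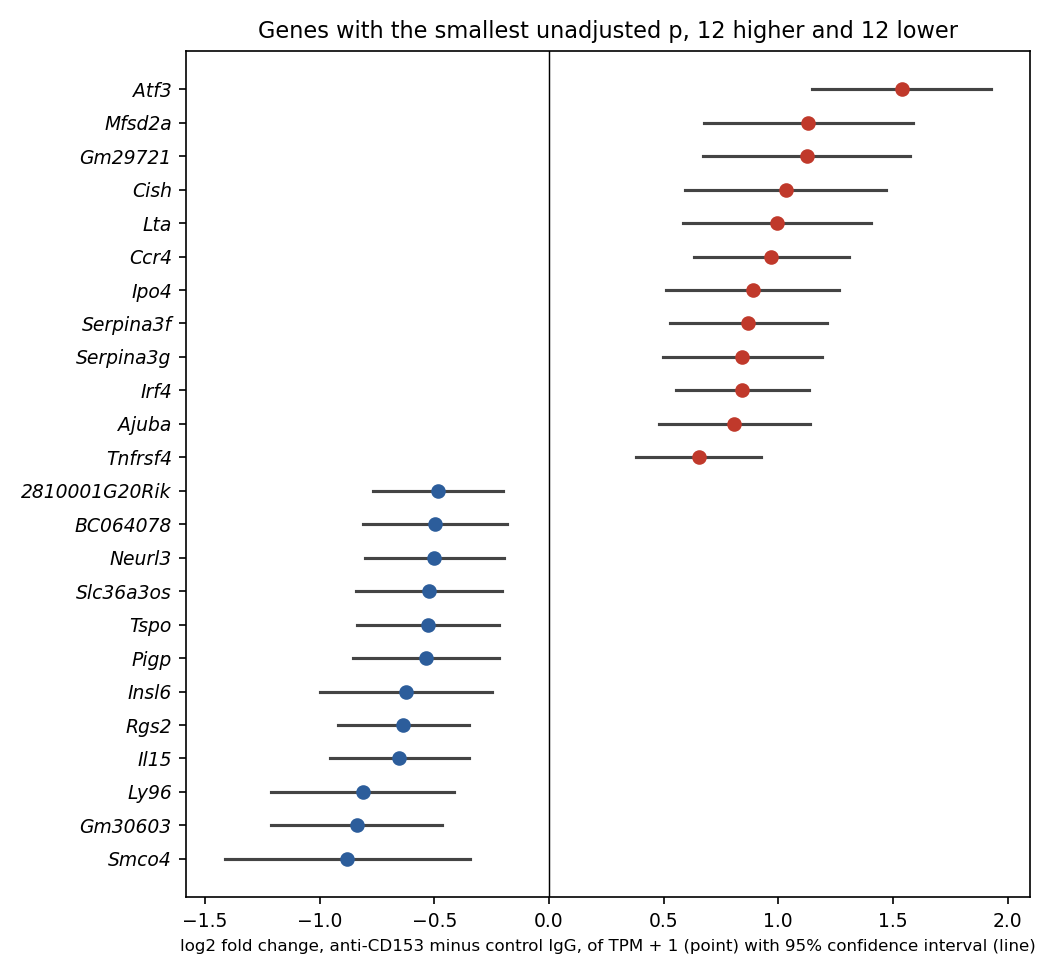
Log2 fold change of TPM + 1, anti-CD153 minus control IgG (horizontal axis), for the 12 genes with the smallest unadjusted p among those higher in all 3 anti-CD153 libraries (red) and the 12 among those lower in all 3 (blue), each with a mean of at least 5 TPM in the higher group; points are limma estimates and lines their 95% confidence intervals. The estimates run from -0.88 for Smco4 to 1.54 for Atf3, and none of the 24 genes passed the adjusted threshold.

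The authors' deposited table carries its own adjusted p for each gene, from a test that the sources used here do not name. By that column 25 genes had an adjusted p under 0.05, and their deposited TPM were higher with anti-CD153 for 20 and lower for 5. Of these, 24 were tested here, all with an unadjusted limma p under 0.05 and with non-overlapping groups, and 21 of them were among the 100 genes with the smallest p in limma. Atf3 had the smallest value in the authors' deposited table, 5.91e-07, followed by Il2ra and Myc at 0.00370 each, Scg2 at 0.00959 and Ccr4 at 0.0103. In the authors' deposited table Cish, Irf4 and Lta stood at 0.0116, Pim2, Ipo4, Mfsd2a and Gm29719 at 0.0144, Slc13a3 at 0.0183, Gbp5 at 0.0233, Serpina3f and Gm45927 at 0.0300, Serpina3g and Sytl3 at 0.0315 and Ajuba at 0.0359. The 5 lower genes in the authors' deposited table were Smco4 (0.0268), Gm33104 (0.0304), Ly96 (0.0315), Rgs2 (0.0395) and S100a4 (0.0410). Tenm4 (0.0304 in the authors' deposited table) was not tested here because its mean was 0.0787 TPM with anti-CD153 and 0.0144 TPM with control IgG.

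Several genes of the authors' deposited table outside the groups named so far had large TPM differences. Scg2, which encodes the secretory granule protein secretogranin II, stood at 239 ± 7.11 against 106 ± 35.4 TPM, and the kinase gene Pim2, a STAT5 target, at 220 ± 16.6 against 110 ± 28.7 TPM. Sytl3 stood at 48.0 ± 1.04 against 23.0 ± 7.68 TPM. S100a4, which encodes a calcium-binding protein of memory T cells, stood at 223 ± 22.3 TPM with anti-CD153 and 445 ± 193 TPM with control IgG (log2 -0.91), or -0.58 without control IgG replicate 1. Exons of another gene model cover 51.7% of the exon bases of S100a4. Gm45927 spans the positions of Clk2 and Scamp3, and Gm29719 is a transcribed pseudogene, so their values are uncertain.

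Of 42 gene lists fixed beforehand, 39 had at least 4 tested members, and 14 of them passed an adjusted p of 0.05 by camera with a preset correlation of 0.01, 13 up and 1 down with anti-CD153. None of the 14 calls held with an estimated correlation. That setting also uses fewer degrees of freedom, which by itself raises p. By fry, which tests whether the genes of a list move one way on balance, the Th2 genes (adjusted p = 0.00422), the T cell cytokines (0.0141) and the STAT5 targets (0.0462) passed. Counts of members past the threshold are given as adjusted over the list alone, and no member of any list passed when adjusted over all genes tested. Ranges of a list's adjusted p are over the other settings of camera with the preset correlation.

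Genes of ribosome biogenesis, many of them targets of MYC, rose with anti-CD153 (camera adjusted p = 4.98e-13, and adjusted p = 0.378 with an estimated correlation). All 26 measured members were higher, with a median log2 fold change of 0.55, and 16 passed when adjusted over the list alone while 10 did not. Rrp12, a ribosome export factor, stood at 9.32 ± 0.202 against 5.01 ± 1.38 TPM, and Srm, which encodes spermidine synthase, at 119 ± 13.0 against 71.3 ± 19.1 TPM. Nop16 (log2 0.57, or 0.38 with array weights) and Rrp1b (0.56), both nucleolar proteins, also passed when adjusted over the list alone. The mean of this list in control IgG replicate 1 lay at -0.25 from the control mean, and that of the other control libraries at 0.06 and 0.19. All 3 anti-CD153 libraries lay between 0.50 and 0.54.

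Targets of IL-2 signalling through STAT5 also rose (camera adjusted p = 1.41e-09, and adjusted p = 0.341 with an estimated correlation). Of 15 measured members 14 were higher, the median log2 fold change was 0.59, and 9 passed when adjusted over the list alone while 6 did not. Those with the smallest p were Lta, Cish, Il2ra (log2 1.11) and Prdm1, which encodes the transcription factor BLIMP-1 and stood at 29.2 ± 4.42 against 17.1 ± 1.09 TPM (log2 0.73, or 0.46 with array weights).

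Early-response genes of the T cell receptor rose as a list (camera adjusted p = 4.76e-05, and adjusted p = 0.378 with an estimated correlation), with 19 of 21 members higher and a median of 0.38, or 0.24 without control IgG replicate 1. When adjusted over the list alone, Irf4, Il2ra and Myc (log2 1.45, or 0.90 with array weights, chromosome 15, 61985341 to 61990361) passed and 18 members did not. Ier2, an immediate-early gene, stood at 409 ± 33.1 against 296 ± 57.9 TPM, a log2 difference of 0.48, or 0.32 without control IgG replicate 1. NF-kB target genes rose by camera (adjusted p = 0.0104, and adjusted p = 0.548 with an estimated correlation), with 16 of 19 members higher and a median of 0.24, or 0.16 without control IgG replicate 1, 0.14 with quantile normalization and with gene-by-gene weights, and 0.11 with the length and GC trend removed. Only Bcl2l1, which encodes the survival protein BCL-XL, passed when adjusted over the list alone, at 62.0 ± 3.25 against 33.8 ± 9.56 TPM (log2 0.89, or 0.58 with array weights). Nfkb2 (log2 0.78), Relb (0.53) and Tnfrsf9 (0.75, or 0.43 without control IgG replicate 1, 0.41 with array weights and 0.47 with gene-by-gene weights), which encodes the costimulatory receptor 4-1BB, did not pass. The NF-kB call was lost without control IgG replicate 3 (adjusted p = 0.0605) and with array weights (0.0918, median 0.13), and its adjusted p ran from 0.00295 to 0.0918 over the other settings of camera.

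T cell cytokine genes rose as a list by camera (adjusted p = 0.00473, and adjusted p = 0.341 with an estimated correlation). Of 16 members 12 were higher, the median was 0.35, and Lta and Il10 passed when adjusted over the list alone while 14 did not. Il10, which encodes an immunosuppressive cytokine, stood at 254 ± 30.1 against 173 ± 19.8 TPM (log2 0.56, or 0.35 with array weights), and Tnf, a neighbour of Lta on chromosome 17, at 77.7 ± 12.9 against 53.4 ± 7.12 TPM (log2 0.53). The call was lost without control IgG replicate 3 (adjusted p = 0.0605), within a range of 6.56e-04 to 0.0605 over the other settings.

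Genes of Th2 cells rose (camera adjusted p = 0.00158, and adjusted p = 0.341 with an estimated correlation). Of 7 members 6 were higher, and the median was 0.45, or 0.21 with no filter on TPM and 0.71 with the length and GC trend removed. When adjusted over the list alone, Ccr4, Il4ra (log2 0.79) and Ccr8 (0.70, or 0.34 with array weights and 0.45 with gene-by-gene weights) passed. Of these, Ccr4 and Ccr8 are chemokine receptors and Il4ra encodes the receptor chain for IL-4 and IL-13, while the cytokine gene Il4 stood at 35.0 ± 6.94 against 25.4 ± 5.55 TPM with overlapping groups (log2 0.45, or 0.79 with that trend removed). Genes of regulatory T cells rose (camera adjusted p = 8.93e-04, and adjusted p = 0.378 with an estimated correlation), with 11 of 13 members higher and a median of 0.29. Il2ra, Il10, Gpr83 (log2 0.73, or 0.34 with a pseudocount of 5) and Ctla4, which encodes an inhibitory receptor and stood at 806 ± 91.0 against 597 ± 42.9 TPM (log2 0.43, or 0.27 with array weights), passed when adjusted over the list alone, and 9 members did not. Activated T cells of other types also express Il2ra, Il10 and Ctla4.

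Inhibitory receptor and exhaustion genes rose by camera (adjusted p = 0.0120, and adjusted p = 0.598 with an estimated correlation), with 13 of 17 members higher and a median of 0.26. Prdm1 passed when adjusted over the list alone, and 16 members did not. Btla stood at 179 ± 13.9 against 127 ± 16.5 TPM (log2 0.50), and Cd200 at 547 ± 50.3 against 379 ± 124 TPM (log2 0.58, or 0.30 without control IgG replicate 1). The call was lost without control IgG replicate 1 (adjusted p = 0.111) and with the length and GC trend removed (0.0524), within a range of 0.00165 to 0.111 over the other settings. The median was 0.42 without control IgG replicate 3. The mean of this list in control IgG replicate 1 lay at -0.25 from the control mean.

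For cholesterol biosynthesis (camera adjusted p = 4.76e-05, and adjusted p = 0.548 with an estimated correlation), 22 of 23 members were higher and the median was 0.33, or 0.17 without control IgG replicate 1 and 0.19 with array weights. Srebf2, the master regulator of the pathway, stood at 88.1 ± 7.98 against 53.7 ± 16.3 TPM (log2 0.74, or 0.47 with array weights) and the enzyme gene Mvd at 11.2 ± 0.520 against 7.32 ± 0.895 TPM (log2 0.56). For glycolysis (camera adjusted p = 3.27e-04, and adjusted p = 0.598 with an estimated correlation), all 20 members were higher and the median was 0.29, or 0.16 without control IgG replicate 1. Slc2a1, which encodes the glucose transporter GLUT1, stood at 51.4 ± 3.80 against 37.7 ± 8.52 TPM (log2 0.46, or 0.26 without control IgG replicate 1), and Pfkm, which encodes a phosphofructokinase, at log2 0.42, or 0.28 with the length and GC trend removed and 0.26 with a pseudocount of 5. No member of either list passed when adjusted over the list alone. The means of these lists in control IgG replicate 1 lay at -0.29 for cholesterol biosynthesis and -0.34 for glycolysis from the control mean.

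For the unfolded protein response (camera adjusted p = 0.00242, and adjusted p = 0.613 with an estimated correlation), 18 of 20 members were higher, the median was 0.32, or 0.16 without control IgG replicate 1 and 0.18 with array weights of either kind, and none passed when adjusted over the list alone. Calr, which encodes the chaperone calreticulin, stood at 872 ± 29.8 against 595 ± 151 TPM (log2 0.58, or 0.35 without control IgG replicate 1), and Sdf2l1 at log2 0.40. For amino acid response genes, targets of ATF4 (camera adjusted p = 0.0334, and adjusted p = 0.598 with an estimated correlation), 15 of 19 members were higher, the median was 0.25, or 0.13 without control IgG replicate 1, and none passed when adjusted over the list alone. Sesn2 (log2 0.75), Shmt2 (0.60), Psat1 (0.72) and Slc7a5 (0.79) had the smallest p, and without control IgG replicate 1 Psat1 stood at 0.43 and Slc7a5 at 0.47, while Slc7a5 was at 0.48 with array weights. This call was lost without control IgG replicate 3 (adjusted p = 0.0589), anti-CD153 replicate 2 (0.0533) or anti-CD153 replicate 3 (0.0567), with the stricter filter on TPM (0.0690), with NM accessions only (0.0843) and with the length and GC trend removed (0.148, median 0.11), within a range of 0.0126 to 0.148. The means in control IgG replicate 1 lay at -0.31 for the unfolded protein response and -0.23 for the amino acid response.

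Genes of S phase and DNA replication rose by camera (adjusted p = 3.76e-05, and adjusted p = 0.598 with an estimated correlation), with 27 of 28 members higher and a median of 0.45, or 0.16 without control IgG replicate 1, 0.27 with a pseudocount of 5 and 0.21 with gene-by-gene weights. None passed when adjusted over the list alone. Mcm5, a subunit of the replicative helicase, stood at 74.9 ± 10.6 against 44.1 ± 16.5 TPM (log2 0.82, or 0.48 without control IgG replicate 1), Mcm3 at log2 0.77 (0.42 without it), Mcm2 at 0.65 (0.36 without it) and Uhrf1 at 0.68. With array weights Mcm5 was at 0.50, Mcm3 at 0.47 and Uhrf1 at 0.28, and with gene-by-gene weights Mcm3 was at 0.51 and Uhrf1 at 0.43. The call was lost with array weights (adjusted p = 0.433, median 0.16), within a range of 3.59e-08 to 0.433 with the preset correlation. In control IgG replicate 1 the mean of this list lay at -0.40 and that of the G2 and mitosis list at -0.48 from the control mean. For S phase, control IgG replicates 2 and 3 lay at 0.32 and 0.07. The anti-CD153 libraries lay between 0.25 and 0.55, so the groups overlapped.

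Cytosolic ribosomal protein genes were the list that fell (camera adjusted p = 1.00e-05, and adjusted p = 0.613 with an estimated correlation), with 23 of 25 members lower, a median of -0.22, and none past when adjusted over the list alone. Rps14 stood at 1144 ± 107 against 1619 ± 564 TPM, and Rpl13 at 2170 ± 235 against 2715 ± 537 TPM, with overlapping groups. Their log2 differences were -0.45 and -0.31, or -0.18 and -0.15 without control IgG replicate 1. With the length and GC trend removed the median was -0.075 with 18 of 25 members lower, Rps14 was at -0.23 and Rpl13 at -0.14. The call was lost without control IgG replicate 1, where the median was -0.0065 (adjusted p = 0.294, within a range of 3.44e-11 to 0.294). The median was -0.41 without control IgG replicate 3, -0.33 without anti-CD153 replicate 2 and -0.11 with gene-by-gene weights, where Rps14 was at -0.30. In control IgG replicate 1 the mean of this list lay at 0.44 and that of the mitochondrially encoded genes at 0.57 above the control mean. For ribosomal proteins, control IgG replicates 2 and 3 lay at -0.10 and -0.33. The anti-CD153 libraries lay between -0.35 and -0.03, so the groups overlapped. Ribosomal protein genes have many processed pseudogenes, so their values are uncertain.

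**Figure D3:**
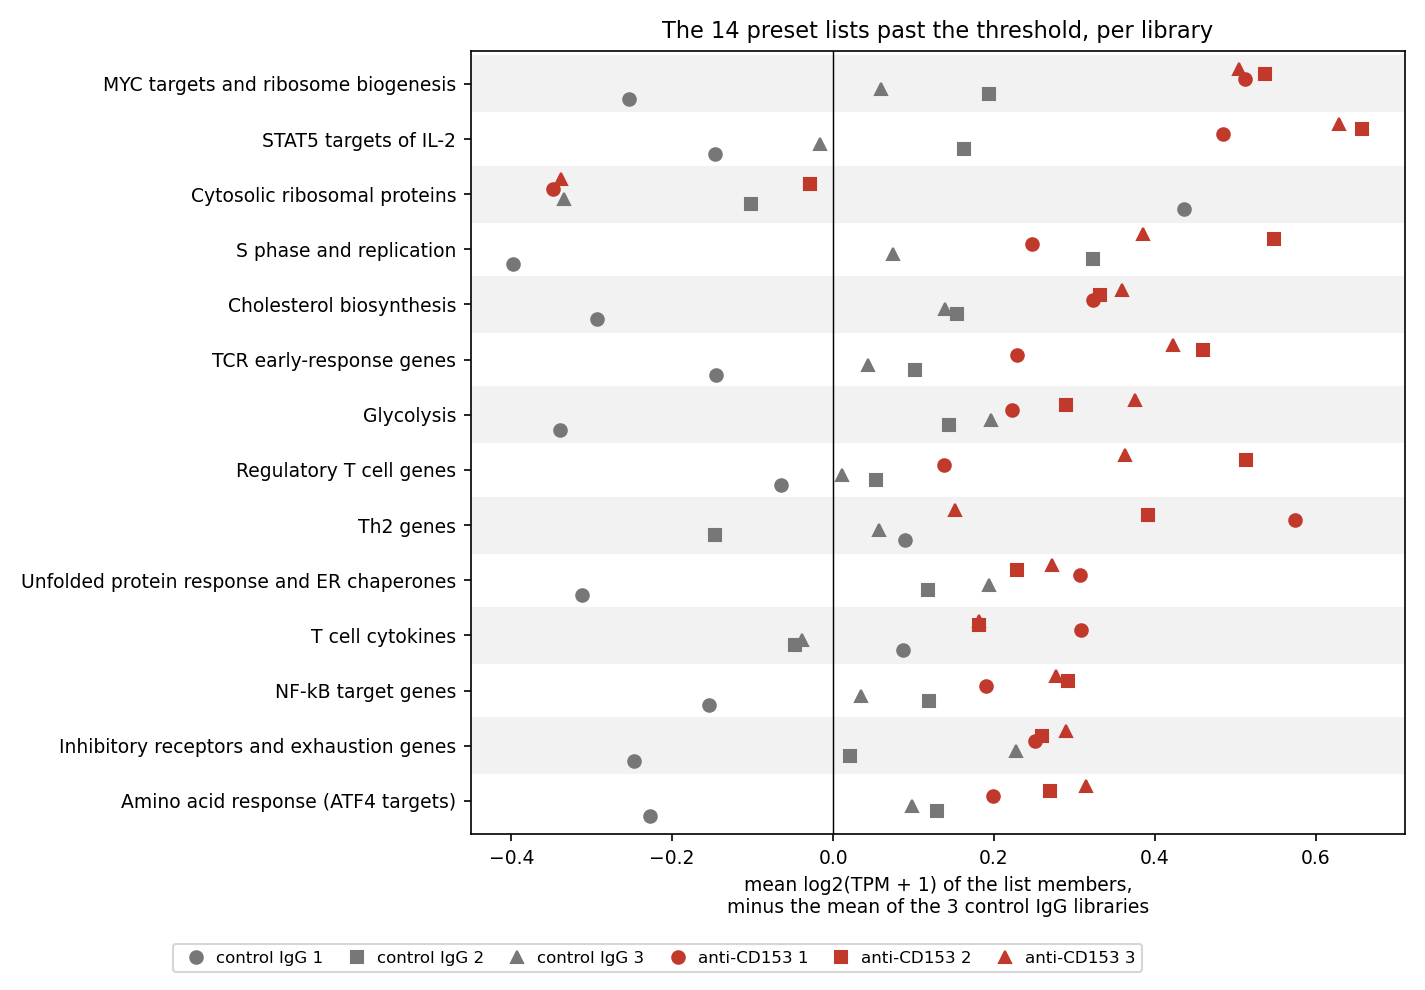
Mean log2(TPM + 1) of the members of each of the 14 gene lists past the threshold, minus the mean of the 3 control IgG libraries (horizontal axis), with 1 point per library (grey, control IgG; red, anti-CD153; circle, square and triangle, replicates 1, 2 and 3). The anti-CD153 points of ribosome biogenesis lie between 0.50 and 0.54, control IgG replicate 1 lies at -0.40 for S phase and at 0.44 for cytosolic ribosomal proteins. For S phase and for cytosolic ribosomal proteins the points of the groups overlap.

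Markers of other splenic cells were compared as levels. Of the B cell genes, Ighm stood at 864 ± 140 TPM with anti-CD153 and 826 ± 211 TPM with control IgG, Igkc at 140 ± 33.0 against 219 ± 99.1 TPM, Cd74 at 27.4 ± 5.71 against 21.7 ± 3.92 TPM and Cd79a at 1.02 ± 0.156 against 1.18 ± 0.425 TPM. The myeloid genes Lyz2 and Cd68 stood at 3.07 ± 1.01 against 2.87 ± 1.44 TPM and at 22.1 ± 3.92 against 19.1 ± 2.06 TPM. Of the CD8 and NK cell genes, Cd8a stood at 1.38 ± 0.656 against 1.38 ± 0.593 TPM, Cd8b1 at 16.6 ± 0.799 against 16.7 ± 0.696 TPM and Klrd1 at 9.33 ± 4.08 against 12.8 ± 6.33 TPM. For each of these 9 genes the difference was smaller than the larger SD of the 2 groups. Of all 36 markers of other cells in the table, 4 differed by more, all under 1 TPM: Klrk1 (0.451 ± 0.125 against 0.846 ± 0.0728 TPM), Klre1 (0.5005 ± 0.0704 against 0.652 ± 0.129 TPM), Itga2b (0.476 ± 0.122 against 0.690 ± 0.0792 TPM) and Fcer2a (0.241 ± 0.0956 against 0.135 ± 0.0307 TPM).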

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

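The transcript length and GC trend, NM accession only, robust eBayes and gene-by-gene array weight alternatives were chosen after seeing the data. With array weights 1699 genes passed the adjusted threshold (1070 higher, 629 lower) and 4601 had an unadjusted p under 0.05. The weights ran from 0.138 (control IgG replicate 1) to 6.71 (anti-CD153 replicate 3). Control IgG replicate 2 had 3.80 and the rest 0.62 to 0.70. Values with array weights therefore rest largely on control IgG replicate 2 and anti-CD153 replicate 3. Why the weights differ was not tested. With these weights estimated gene by gene, 2 genes passed (Atf3 and Irf4), 2015 had an unadjusted p under 0.05 and 16 lists passed, so the count of 1699 depends on how the weights are estimated. Leaving out each library in turn gave 0 to 1 genes past the threshold, the 1 gene being Traj53, lower, without anti-CD153 replicate 2 and named after its value was seen. It gave 458 to 1487 genes at an unadjusted p under 0.05, and 12 to 16 lists. Of the lists, 0 passed with an estimated correlation and 3 by fry, which asks another question. In a fit with a replicate block, 0 genes passed, 860 had an unadjusted p under 0.05 and 14 lists passed. Under the other alternatives 0 genes passed. Of the 113 named genes under up to 19 alternatives each, 2041 results kept their direction and side of the threshold, 86 passed it with array weights, 2 with gene-by-gene weights, and 2 changed sign: with array weights Cd44 was at 0.045, and without control IgG replicate 1 Pdcd1 was at -0.0046 (range -0.0046 to 0.50 over the libraries left out); the cause was not tested. Values of named genes moved by over 1.5 times for 38 with array weights (Myc to 0.90, Spp1 to 0.13, Il2 to 0.84), 27 without control IgG replicate 1, 16 with a pseudocount of 5, which pulls low values together by construction, 16 with the length and GC trend removed, 13 with gene-by-gene weights, and 2 to 4 under each of the other alternatives that moved any. For the 14 lists, 256 results kept their call and 38 lost it (14 with an estimated correlation, 11 by fry), with 0 changes of direction. Robust eBayes was applied to the p of single genes only, so its list results equal the main ones by construction. Limma without a trend, robust eBayes and the replicate block leave each log2 fold change as it was, so no gene could change direction there. The depth behind these TPM values is unknown, so what depth limits cannot be stated.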

Other observations

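The tests of other-cell markers in control IgG replicate 1, of the length and GC trend for the share of higher genes, of the splits with array weights of either kind and of the splits list by list were chosen after the results were seen.

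Further lists did not pass the threshold by camera with all libraries, and their genes are given as values. Among SA-T cell markers (adjusted p = 0.105, 9 of 13 higher), Tbx21, which encodes the Th1 factor T-bet, stood at 44.6 ± 2.46 TPM with anti-CD153 against 26.9 ± 7.32 TPM with control IgG, and Rgs16 at a log2 difference of 0.57, or 0.29 without control IgG replicate 1 and with array weights and 0.34 with gene-by-gene weights. Among interferon gamma response genes (adjusted p = 0.133, 16 of 21 higher), only Gbp5, a guanylate-binding protein of host defence, passed when adjusted over the list alone (adjusted p = 0.0313), with a log2 difference of 1.30, or 0.62 with array weights, and it did not pass over all genes. Socs1 stood at a log2 difference of 0.50, or 0.24 with array weights, Socs3 at 0.47 and Tap1 at 0.36, or 0.22 without control IgG replicate 1 and with array weights and 0.21 with the length and GC trend removed. Type I interferon genes had a median of -0.09 with 14 of 21 lower (adjusted p = 0.0823), with Rsad2 at -0.40 and Ifit3 at -0.34, both under 2 TPM. With a pseudocount of 5 these were -0.16 and -0.13, and with one of 0.1 they were -0.62 and -0.54, while Rsad2 was at -0.25 with array weights. In the TNF superfamily (adjusted p = 0.163, 11 of 17 higher), Tnfrsf4 passed when adjusted over the list alone (adjusted p = 0.00963) and not over all genes, and Tnfrsf1b, a TNF receptor, stood at 0.60, or 0.39 without control IgG replicate 1. Among chemokine and homing receptors (adjusted p = 0.481, 11 of 15 higher), Ccr4 and Ccr8 passed when adjusted over the list alone, and Cxcr4 stood at -0.30, or -0.15 with array weights. In the apoptosis and survival list (adjusted p = 0.957), Bcl2l1 passed when adjusted over the list alone (adjusted p = 0.0399) and Bcl2, a survival gene, stood at 68.1 ± 3.83 against 48.4 ± 7.46 TPM.

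Among follicular helper genes (adjusted p = 0.297, 11 of 15 higher), the costimulatory receptor gene Icos stood at 652 ± 25.4 against 516 ± 29.8 TPM and Sh2d1a, which encodes the adaptor SAP, at 295 ± 6.44 against 398 ± 61.7 TPM, although 26.6% of the exon bases of Sh2d1a overlap Tenm1 on the opposite strand. The log2 difference of Sh2d1a was -0.42, or -0.19 with the length and GC trend removed. Naive and memory T cell genes went both ways, with Satb1 at 0.60 (0.32 with a pseudocount of 5), Il7r at -0.48 (-0.27 with array weights) and Lef1 at -0.27. Their median was -0.02 and their mean 0.01, camera gave an adjusted p of 0.542, and the mixed test of fry, which asks for changes in either direction, gave 0.0188. That mixed test passed 8 of the 39 lists, so this result is not particular to them. The others were STAT5 targets, T cell receptor early-response and Th2 genes (0.0188 each), regulatory T cell genes (0.0287), cytokines (0.0309), and ribosome biogenesis and the TNF superfamily (0.0429 each). Th17 genes had an adjusted p of 0.169, with Il12rb1 at 0.51, or 0.31 with array weights. Th1 genes had an adjusted p of 0.957, tested as lower with a median of -0.01 and a mean of 0.05. The list of CD153 partners and the T cell receptor complex had an adjusted p of 0.714, with Zap70 at 0.41 and Ptprc, which encodes CD45, at 0.38, or 0.24 without anti-CD153 replicate 1 and with array weights. The remaining adjusted p were 0.105 for senescence secretory genes, 0.142 for mitochondrially encoded genes, 0.154 for cytosolic heat shock, 0.182 for nuclear oxidative phosphorylation genes, 0.293 for fatty acid synthesis, 0.858 for hypoxia targets and 0.9995 for G2 and mitosis. Chemokines (0.626, median 0.05, mean -0.01), p53 targets (0.714, median 0.04) and cytotoxic genes (0.858, median 0.04) were tested as lower, since camera compares a list with the other genes. The marker lists had an adjusted p of 0.752 for B cells, 0.761 for CD8 and NK cells, 0.835 for macrophages and 0.957 for dendritic cells, whose genes Ccr7 and Bst2 T cells also express.

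Some of these lists passed by camera under an alternative, and the ranges given are those with the preset correlation. Genes of G2 and mitosis passed as lower without control IgG replicate 1 (adjusted p = 0.00123), with array weights (3.35e-05) and with gene-by-gene weights (0.00188), and as higher without control IgG replicate 2 (0.0427), within a range of 3.35e-05 to 0.9995. Mitochondrially encoded genes passed as higher without control IgG replicate 1 (0.0201) and as lower without control IgG replicate 2 (0.0427) or 3 (0.00190), within a range of 0.00190 to 0.989. Type I interferon genes passed as lower without anti-CD153 replicate 1 (0.00321), with no filter (0.0268), with the length and GC trend removed (0.0119) and with NM accessions only (0.0317), within a range of 0.00321 to 0.446. Senescence secretory genes passed as higher without control IgG replicate 1 (0.00136), with the trend removed (9.29e-04), with array weights (0.0281), with gene-by-gene weights (0.00559) and with quantile normalization (0.0299), within a range of 9.29e-04 to 0.618. SA-T cell markers passed as higher without anti-CD153 replicate 2 (0.0483) and with quantile normalization (0.0300), within 0.0300 to 0.254, and interferon gamma response genes without anti-CD153 replicate 2 (0.0288), within 0.0288 to 0.732. With array weights alone, follicular helper genes passed as higher (0.0109, within 0.0109 to 0.707) and nuclear oxidative phosphorylation genes as lower (0.00894, within 0.00894 to 0.915).

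Control IgG replicate 1 lay apart from the other 5 libraries. Over the 12409 genes with a transcript length, its distance was 1.87 times the next largest, and still 1.77 times once the trend of transcript length and GC content was removed, which argues against that trend as the whole cause. Cells of another type, which the enrichment for CD4, CD153, PD-1 and high CD44 selects against, cannot be told apart from other sources, since their markers went both ways within each tested list, and those of plasma cells, neutrophils and of erythroid cells and platelets were not tested there. The highest list median in that library was 0.19 above the others, for dendritic cells, with -0.28 for B cells, -0.29 for macrophages and -0.10 for CD8 and NK cells, while Igkc lay 1.06 and Klrd1 1.30 above the others. A difference in the state of the cells or in the RNA of that library stays open, and no biological explanation was tested, since the labels name no difference between replicates.

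A total of 14 lists passed by camera. Control IgG replicate 1 as the only source of the calls is argued against, since 12 of the 14 passed without it. The sizes depended on it more. Without it the median went from 0.45 to 0.16 for S phase, 0.33 to 0.17 for cholesterol biosynthesis, 0.32 to 0.16 for the unfolded protein response and 0.29 to 0.16 for glycolysis. That of STAT5 targets went from 0.59 to 0.54 and that of Th2 genes from 0.45 to 0.52. The length and GC trend as the only source of the calls is also argued against, since 12 passed with it removed, although the median of ribosomal proteins went from -0.22 to -0.075. For 12 lists the estimated correlation between members ran from 0.105 to 0.959, and variation shared by their members between libraries stays open. For Th2 genes and T cell cytokines it was -0.121 and -0.0024, with no spread known for these estimates. Both lie below the preset 0.01. Still, the unadjusted camera p went from 3.64e-04 to 0.0214 for Th2 genes and from 0.00133 to 0.0263 for cytokines. For these lists the size of the estimated correlation was therefore not what raised p. With an estimated correlation, camera takes its degrees of freedom from the libraries rather than from the genes, which by itself raises p. The loss of a call there is therefore not by itself evidence of shared variation.

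More genes were higher than lower at an unadjusted p under 0.05. Control IgG replicate 1 as the only source is argued against by 71.1% higher without it. With the length and GC trend removed the share was 76.4%. That removal kept the level of each library, and the median log2 fold change of all tested genes was 0.058, against 0.055 before. It therefore cannot decide whether the trend contributed to the share. The largest move upon leaving out 1 library was to 59.4%, without anti-CD153 replicate 2. With median-of-ratios scaling the share was 54.3%, but that scaling sets the median of all genes near 0, which moves the share toward even whatever the cause, so the scaling of the libraries cannot be told apart from other sources.

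Of the 10 splits of the 6 libraries into equal groups, 2, the real one included, gave at least as many lists, with 14 for the real split and 16 for the highest other, and 10 splits are too few for a share under 0.05. Of the 14 lists, all but the Th2 genes also passed in at least 1 of the 9 other splits. Ribosomal proteins and glycolysis passed in 6 of them, cholesterol, ribosome biogenesis, the unfolded protein response and S phase in 5, STAT5 targets in 4, the T cell receptor early response, regulatory T cells and inhibitory receptors in 2, and cytokines, NF-kB targets and the amino acid response in 1. The real split gave the smallest unadjusted camera p for 7 of the 14 lists, such as ribosome biogenesis (1.28e-14, against 3.97e-09 as the smallest elsewhere). Other lists had a smaller p in another split, such as ribosomal proteins (7.70e-07 against 6.35e-16), S phase (3.85e-06 against 6.23e-16) and glycolysis (5.87e-05 against 2.70e-06). For the gene counts too, 10 splits are too few for a share under 0.05, and each number of splits includes the real one. The real split gave 0 genes past the adjusted threshold and the highest other 1, and with a real count of 0 all 10 splits give as many by construction. At an unadjusted p under 0.05 the real split gave 1109 genes and the highest other 1908, and 2 splits gave as many. With array weights the real split gave 1699 genes and the highest other 2332, and 2 splits gave as many, but the weights did not converge in 5 of the 10 splits, that of 2332 included, and did in the real one. With gene-by-gene weights the real split gave 2 genes and the highest other 14. Further splits gave 7 and 2, so the count of 2 is not particular to the real split.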
